A study of Homo sapiens with 14 samples.

How the data were processed

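RNA sequencing of 14 libraries of NT2 human embryonal carcinoma cells was analysed from the deposited tables. Per the labels, total RNA was sequenced on an Illumina instrument from untreated cells at day 0 and from cells after 5, 10 and 21 days of retinoic acid (RA) or bone morphogenetic protein 2 (BMP2), with 2 libraries per group. The deposited count table holds raw read counts of 25952 Ensembl genes, made by the authors. The authors' second table holds RPKM of the same genes, reads scaled to gene length and to the counted reads of the library. The submitters' notes name STAR, featureCounts, DESeq2 and build hg19, without versions or the role of each. Among counts from 1 to 19, between 66.0% and 73.5% of each library were even, as where both reads of a pair are counted, so counts exceed the number of fragments. The gene length implied by RPKM was tested on 11016 genes with at least 1000 counts, and it varied by at most 0.74% between libraries. It equalled the whole gene span, introns included, within 1% for 88.0% of the 10936 genes with a span in GENCODE v29. RPKM was therefore used in alternative tests alone. Whether the counts too were made over whole spans is not given in the sources used here, so they may include reads in introns. Gene symbols came from a reference list of gene names, which held 25214 of the 25952 identifiers. For the other 738, the name in GENCODE v29 was used where there was one. That annotation is on another build than hg19, so no coordinates are given. Total counts ran from 45773278 to 75754396 per library, a ratio of 1.65, and 0 pairs of libraries were identical.

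Groups were taken from the sample titles. The RA day 21 descriptions carry other replicate numbers than their titles, and the titles were used. The numbers were not taken to pair libraries of different groups. Each gene was tested with edgeR 4.0.16 in R 4.3.3, with a mean per group over all 14 libraries, TMM factors, filterByExpr with a minimum count of 10, and quasi-likelihood F tests. This kept 19142 genes, which hold 99.99% of the counts. The fit had 7 residual and 3.08 prior degrees of freedom and a common biological coefficient of variation of 0.368. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The SE of a log2 fold change is its size divided by the square root of F. There were 11 comparisons: each of 6 treated groups against day 0, RA against BMP2 at 3 days, and day 21 against day 5 in each treatment. The difference between the treatments was tested directly.

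The design, the gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. The 30 lists hold 520 members, 501 of them in the tables. The list of 13 mitochondrially encoded genes had 0 members there, leaving 29 lists, which were tested in 9 comparisons with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over 261 tests. A second form of camera estimates that correlation from the data, and its adjusted p stands beside each call. The NER genes form 4 of the lists, with 52 members, 51 of them tested. Each list was also adjusted over its own members. Genes were named where they belong to an NER list, where they were among the 6 largest changes in a direction with at least 5 CPM and libraries that do not overlap, where they were among the 4 largest called changes of another list, or where they stood in a fixed set of markers. Some genes that fit this rule, and 1 of the lists, are not reported here. A fold against a group without a count was computed against 3 counts over that group.

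In simulated data, 48 to 50 of 18525 genes changed per fold. Of these edgeR recovered 0% at 1.5-fold, 6.1% at 2-fold, 47.9% at 4-fold and 64% at 8-fold, with 5 false calls. An unchanged comparison gave 0 calls, with 4.81% of p-values under 0.05. Smaller changes can be missed. Rates may differ if more genes change.

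The alternatives were RLE factors, no low-count filter (25952 genes), CPM of at least 1 in 2 libraries (15721 genes), robust dispersions, a replicate block, at least a 2-fold change, DESeq2 1.42.0, and only the 4 libraries compared. limma was run on log2(RPKM + 1) and log2(RPKM + 0.1) of 11641 genes with RPKM of at least 0.5 in 2 libraries. Lists were also tested with fry, which, unlike camera, does not weigh a list against other genes. Each of the 14 libraries was left out in turn, where the lone library of its group is assumed to vary like the other groups. Fits without both BMP2 day 10 libraries and without both RA day 21 libraries, and limma on RPKM divided by the TMM factors, were added after the data were seen. Tables were prepared and figures drawn with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.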

Results

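Gene expression was measured by RNA sequencing in NT2 cells, a human embryonal carcinoma line that can be driven toward several cell fates. Per the labels, retinoic acid (RA) at a final 10 µM was the neuron-inducing treatment and bone morphogenetic protein 2 (BMP2) the muscle-inducing treatment. The study concerns nucleotide excision repair (NER), the pathway that removes bulky DNA lesions such as those of ultraviolet light, during differentiation. The labels name 30 ng/ml as the BMP2 dose first tested and 40 ng/ml as the later one, without giving the dose of each library. The 14 libraries form 7 groups of 2: untreated day 0, and days 5, 10 and 21 of RA and of BMP2. The total counts of replicates 1 and 2 were 50475226 and 75754396 for untreated day 0. They were 49461120 and 67087209 for RA day 5, 45773278 and 60913075 for RA day 10, and 61590693 and 69531635 for RA day 21. The BMP2 libraries held 57193584 and 63039545 counts at day 5, 56805074 and 48707236 at day 10, and 52242740 and 51915458 at day 21. Untreated cultures of later days were not analysed here, so each comparison with day 0 combines the factor with the time in culture.

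Values below are mean CPM of the 2 libraries of a group, counts scaled to the library size times its TMM factor. Log2 fold changes ± SE come from the edgeR fit over all 14 libraries, with Benjamini-Hochberg adjusted p. The labels do not say whether the 2 libraries of a group come from separate cultures, so p-values measure only the spread between these samples. An exact permutation test of 1 group against another, two-sided, cannot go below p = 0.333 here, so no such test is given per gene. Genes without a count in a group are given as at least so many fold, against a floor of 3 counts over that group. Floors cover counting error alone, and not fully, as counts exceed fragments, so these folds can be too high. The medians of lists use these folds. Among the genes named, CYP26A1, TDGF1, LEFTY1, HOXA3, HOXB4, SOX2, ACTA2, ACTC1, ASPN, SNAP25, FOSB, JUNB, XPC, POLD4, RPA3 and ERCC5 have most of their span inside other genes. Their values are uncertain to that extent, since reads of a neighbour can be counted with them. All CPM and fold changes may include reads in introns.

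The first principal component of log2 CPM (38.1% of the variance) ran from untreated day 0 (-140.4 and -138.4) to BMP2 day 21 (125.6 and 139.7), with RA day 21 at 59.2 and 67.7, and the second (20.4%) set RA libraries apart from BMP2 libraries. Replicates of 6 groups correlated across genes with r between 0.987 and 0.998. The BMP2 day 10 replicates stood apart from each other, with r = 0.957. Replicate 1 was closest to BMP2 day 5 replicate 2 (r = 0.996) and replicate 2 to BMP2 day 21 replicate 2 (r = 0.986). BMP2 day 5 replicate 2 was in turn closer to BMP2 day 10 replicate 1 than to its own replicate (r = 0.989), and RA day 10 replicate 2 slightly closer to RA day 5 replicate 1 (r = 0.988) than to its own (r = 0.987). Genes are not independent replicates in these correlations.

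**Figure D1:**
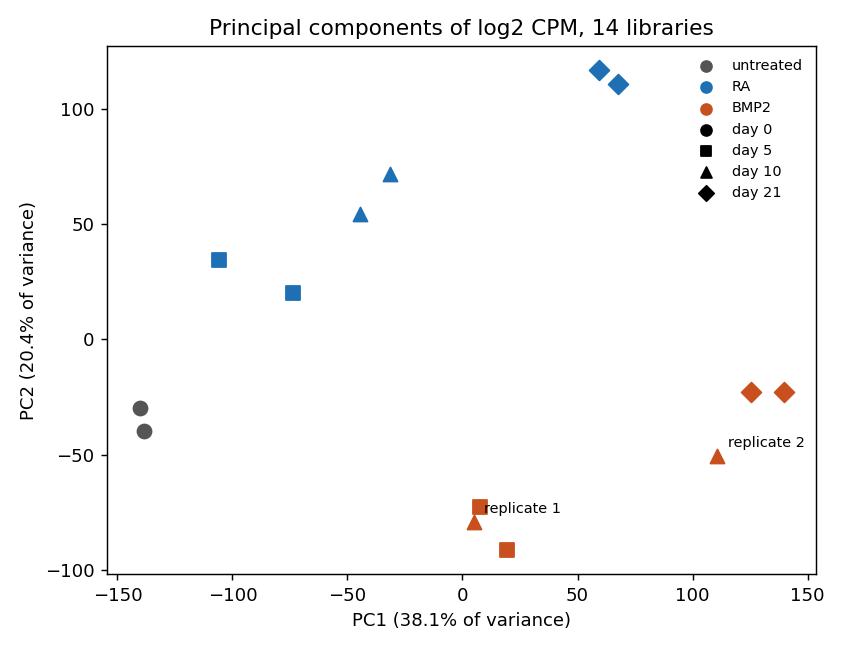
Principal components 1 and 2 of log2 CPM for the 14 libraries, in units of the component score, with colour for the treatment and marker shape for the day. The BMP2 day 10 libraries lie at 4.8 and 110.6 on the first component, the former near the BMP2 day 5 libraries and the latter near those of day 21.

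RA day 5 against untreated day 0 asks which genes moved early in neuron induction. HOX genes, which pattern the body axis, appeared from near silence, HOXA2 at least 1300-fold higher. CYP26A1 and CYP26B1, enzymes that break down RA, rose by 5.11 ± 0.83 and 8.97 ± 1.08 on the log2 scale (adjusted p = 0.0058 for CYP26A1), and the RA receptor gene RARB by 5.78 ± 0.60. NANOG and TDGF1, markers of pluripotent cells, fell, with log2 fold changes of -3.98 ± 0.98 and -4.61 ± 0.63, while POU5F1 had -2.64 ± 1.19 without passing the test (adjusted p = 0.21). The neural transcription factor genes PAX6 and POU3F2 rose, by 4.06 ± 0.65 and 3.35 ± 0.71. Of the 39 HOX genes tested, 25 rose and 0 fell, or 28 and 0 adjusted over the list alone (median log2 fold change 7.33, camera adjusted p = 1.2e-48, adjusted p = 0.16 with an estimated correlation). Of 16 RA response genes, 9 rose and 1 fell, or 12 and 1 adjusted over the list alone (median 3.08, camera adjusted p = 2.1e-19, adjusted p = 0.16 with an estimated correlation). Among 22 pluripotency genes, 8 fell and 2 rose, or 11 and 3 adjusted over the list alone (median -2.20, camera adjusted p = 2.6e-08, adjusted p = 0.32 with an estimated correlation). The 2 that rose were NODAL and LEFTY1, a signalling ligand and an antagonist of it. Of 12 endoderm and liver genes, 2 rose, FOXA1 and GATA6, or 5 with 1 fallen adjusted over the list alone (camera adjusted p = 0.0074, adjusted p = 0.27 with an estimated correlation). Of 13 trophoblast and amnion genes, 2 rose, ISL1 and TFAP2A, or 5 adjusted over the list alone (camera adjusted p = 0.0004, adjusted p = 0.38 with an estimated correlation). Camera also called as higher neural progenitor and proneural (3 of 18 rose, 5 adjusted over the list alone, adjusted p = 0.034), BMP response (5 of 16 rose and 1 fell, 7 and 1 adjusted over the list alone, adjusted p = 0.0047) and smooth muscle and contractile (3 of 14 rose, 3 adjusted over the list alone, adjusted p = 0.0016), and as lower glycolysis (1 of 16 fell, 1 adjusted over the list alone, adjusted p = 0.04), with adjusted p from 0.44 to 0.53 with an estimated correlation. Without 1 library, calls ended for neural progenitor and proneural (0.37), BMP response (0.21), smooth muscle and contractile (0.08) and glycolysis (0.072) genes, with the highest adjusted p in brackets. In all, 1591 of 19142 genes passed the edgeR test, 1070 higher and 521 lower. With limma on RPKM, 594 and 521 were higher and lower (offset 1) and 768 and 393 (offset 0.1). These became 568 and 677, and 715 and 501, with TMM factors. Without 1 library, the edgeR count was 551 (untreated day 0 replicate 1), 345 (untreated day 0 replicate 2), 462 and 943 (RA day 5 replicates 1 and 2), 973 and 979 (RA day 21 replicates 1 and 2), and 2809 and 2810 (BMP2 day 10 replicates 1 and 2). It was 2839 with only the 4 libraries compared and 3236 in DESeq2. Single genes lost their call without untreated day 0 replicate 1 for CYP26A1 (4.65), PAX6 (3.91), POU3F2 (3.08), ISL1 (6.92) and NODAL (3.16), without untreated day 0 replicate 2 for PAX6 (4.24), POU3F2 (3.69), ISL1 (7.59) and NODAL (4.73), without RA day 5 replicate 1 for NODAL (2.59), RA day 5 replicate 2 for POU3F2 (2.83) and RA day 21 replicates 1 and 2 for NODAL (3.75 each), and without any library but those of RA day 21 and BMP2 day 10 for NANOG (-4.28 to -3.71) or any but untreated day 0 replicate 2 and those of BMP2 day 10 for LEFTY1 (2.53 to 3.89), while POU5F1 passed without BMP2 day 10 replicate 1 or 2 (-2.64 each) and with only the 4 libraries compared (-2.61).

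RA day 10 against untreated day 0 addresses the middle of neuron induction. Single neuronal genes now stood above the untreated level: MAP2, a microtubule protein of neurites, rose by 2.51 ± 0.37 on the log2 scale (adjusted p = 0.0018), DCX of migrating neurons by 3.09 ± 0.63 (adjusted p = 0.0076) and the neurofilament gene NEFM by 4.17 ± 0.35, from 30.2 to 544 CPM. The neural factor gene ZIC1 rose by 6.27 ± 0.75. POU5F1 fell from 1010 to 29.5 CPM (-5.10 ± 1.34, adjusted p = 0.022), and OTX2, a forebrain factor gene, had a log2 fold change of -7.72 ± 1.30. Of 25 neuronal genes, 8 rose and 3 fell, or 9 and 4 adjusted over the list alone, and the list was not called (median 0.41, camera adjusted p = 0.084). Of 18 neural progenitor and proneural genes, 5 rose and 1 fell, the same numbers adjusted over the list alone (median 2.36, camera adjusted p = 0.0099, adjusted p = 0.49 with an estimated correlation). Pluripotency genes fell in 14 of 22 cases and rose in 0, or 16 and 0 adjusted over the list alone (median -2.89, camera adjusted p = 4.4e-11, adjusted p = 0.28 with an estimated correlation). HOX genes rose in 28 of 39 cases, or 29 adjusted over the list alone (median 7.62, camera adjusted p = 1.3e-36, adjusted p = 0.17 with an estimated correlation). Of 16 glycolysis genes, 10 fell, or 12 adjusted over the list alone (median -0.95, camera adjusted p = 1.9e-06, adjusted p = 0.28 with an estimated correlation), among them PGAM1 (-1.35 ± 0.16) and LDHA (-1.37 ± 0.33). Further lists called by camera were RA response, BMP response, smooth muscle and contractile, trophoblast and amnion and extracellular matrix genes as higher and mismatch repair, base excision repair, homologous recombination, cell cycle and ribosomal protein genes as lower (adjusted p from 5.2e-11 to 0.047, adjusted p from 0.18 to 0.65 with an estimated correlation). Without 1 library, calls ended for base excision repair (0.055), homologous recombination (0.2), BMP response (0.18), smooth muscle and contractile (0.073), trophoblast and amnion (0.064) and extracellular matrix (0.069) genes, with the highest adjusted p in brackets. In total 4593 genes passed the edgeR test, 2476 higher and 2117 lower, and 2959 of them with at least a 2-fold change. On RPKM, limma called 1987 and 1275 higher and lower (offset 1) and 2219 and 1107 (offset 0.1). Division by TMM factors gave 1279 and 2132, and 1520 and 1975. Without 1 library, the edgeR count was 2426 (untreated day 0 replicate 1), 1500 (untreated day 0 replicate 2), 1856 (RA day 10 replicate 1) and 2913 (RA day 10 replicate 2). Gene calls ended without untreated day 0 replicates 1 and 2 for LDHA (-1.37 and -1.36) and POU5F1 (-5.09 and -5.10), and without RA day 10 replicate 1 for LDHA (-1.19) and POU5F1 (-5.44) and replicate 2 for POU5F1 (-4.78).

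RA day 21 against untreated day 0 describes the end of neuron induction. Pluripotency genes had mostly fallen: POU5F1 (ENSG00000204531) fell from 1010 to 0.402 CPM (-11.29 ± 1.77, adjusted p = 0.00083), NANOG (ENSG00000111704) from 249 to 0.199 CPM (-10.31 ± 1.34) and LIN28A from 2790 to 1.88 CPM (-10.54 ± 1.91). PAX6 rose by 4.53 ± 0.67 and MAP2 by 2.24 ± 0.37, while DCX stood at -1.24 ± 0.60 without passing (adjusted p = 0.12) and the secretory granule gene SCG3 fell, at -7.78 ± 1.13. CYP26B1 reached 865 CPM from 0.213 (11.97 ± 1.19). COL3A1, a fibrillar collagen gene, rose from 1.63 to 5350 CPM (11.72 ± 2.11, adjusted p = 0.0017), and HOXA3 was at least 6900-fold higher. Of 22 pluripotency genes, 20 fell, as many as adjusted over the list alone (median -5.80, camera adjusted p = 1e-15, adjusted p = 0.27 with an estimated correlation). Of 28 cell cycle genes, 27 fell, or 28 adjusted over the list alone (median -2.10, camera adjusted p = 7.3e-14, adjusted p = 0.42 with an estimated correlation), with CDC6 at -2.84 ± 0.35 and the proliferation marker MKI67 at -1.96 ± 0.39. CDKN1A, the cell cycle inhibitor p21, rose by 4.28 ± 1.22, and the ubiquitin ligase gene MDM2 stood at 0.06 ± 0.47 (adjusted p = 0.94). Of 25 neuronal genes, 7 rose and 9 fell, the same numbers adjusted over the list alone (median -0.95, camera adjusted p = 0.87). Of 21 extracellular matrix genes, 13 rose and 1 fell, or 15 and 1 adjusted over the list alone (median 2.80, camera adjusted p = 0.0011, adjusted p = 0.50 with an estimated correlation). Of 16 glycolysis genes, 13 fell, as many as adjusted over the list alone (median -1.45, camera adjusted p = 8.1e-08, adjusted p = 0.27 with an estimated correlation). Camera also called HOX and RA response genes as higher (adjusted p from 6.1e-20 to 1.7e-05, adjusted p = 0.27 with an estimated correlation). The edgeR test passed 8529 genes, 4487 higher and 4042 lower. Higher and lower calls of limma on RPKM were 3407 and 2739 (offset 1) and 3539 and 2722 (offset 0.1). They were 2812 and 3258, and 2961 and 3258, with TMM factors. With 1 library left out, the edgeR count was 5426 (untreated day 0 replicate 2), 5470 (RA day 21 replicate 1) and 5271 (RA day 21 replicate 2). The call of CDKN1A ended without untreated day 0 replicates 1 and 2 (4.08 and 4.52) and RA day 21 replicate 2 (3.93), and DCX passed without untreated day 0 replicate 2 (-1.92).

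BMP2 day 5 against untreated day 0 addresses the start of muscle induction. Smooth muscle genes rose: ACTA2 (ENSG00000107796), smooth muscle actin, from 0.876 to 263 CPM (log2 fold change 8.21 ± 0.96, adjusted p = 0.00045), MYOCD, a co-activator of smooth muscle genes, by 7.21 ± 0.83, and CNN1 by 2.66 ± 0.62. The cardiac genes ACTC1 and TNNT2 rose too, by 6.47 ± 1.21 and 3.39 ± 1.11, and HAND1, a factor gene of heart, amnion and trophoblast, rose from 0.498 to 525 CPM (9.97 ± 1.64). MSX1 and MSX2, targets of BMP signalling, rose by 9.09 ± 1.22 and 3.86 ± 0.79, while ID1 and ID3 stood at -0.01 ± 0.35 (adjusted p = 1) and 0.07 ± 0.38 (adjusted p = 0.92). POU5F1 and NANOG fell, at -3.93 ± 1.27 and -4.50 ± 1.00. Of 14 smooth muscle and contractile genes, 12 rose, as many as adjusted over the list alone (median 2.78, camera adjusted p = 6e-08, adjusted p = 0.28 with an estimated correlation). Of 16 BMP response genes, 10 rose, or 11 adjusted over the list alone (median 3.10, camera adjusted p = 1.5e-07, adjusted p = 0.35 with an estimated correlation). Of 17 cardiac muscle genes, 8 rose and 1 fell, the same numbers adjusted over the list alone, and the list was not called (median 1.23, camera adjusted p = 0.15). Of 19 skeletal muscle genes, 5 rose and 2 fell, the same numbers adjusted over the list alone (median 0.02, with a test pointing down, camera adjusted p = 0.93). Of 13 trophoblast and amnion genes, 6 rose, or 7 adjusted over the list alone (median 5.28, camera adjusted p = 0.00066, adjusted p = 0.41 with an estimated correlation). Of 21 extracellular matrix genes, 17 rose and 1 fell, the same numbers adjusted over the list alone (median 2.87, camera adjusted p = 8.4e-09, adjusted p = 0.32 with an estimated correlation). Of 22 pluripotency genes, 17 fell, as many as adjusted over the list alone (median -3.59, camera adjusted p = 3.5e-12, adjusted p = 0.27 with an estimated correlation). HOX genes rose in 27 of 39 cases and fell in 1, or 29 and 1 adjusted over the list alone (median 3.65, camera adjusted p = 8.7e-12, adjusted p = 0.32 with an estimated correlation). Other lists that camera called were epithelial genes as higher and mismatch repair, base excision repair, homologous recombination, cell cycle and glycolysis genes as lower (adjusted p from 5.8e-06 to 0.03, adjusted p from 0.41 to 0.56 with an estimated correlation). Without 1 library, calls ended for homologous recombination (0.096) and epithelial (0.11) genes, with the highest adjusted p in brackets. With edgeR, 5597 genes passed, 3039 higher and 2558 lower. Tested by limma, RPKM gave 1692 and 2223 higher and lower (offset 1) and 1992 and 2097 (offset 0.1). After division by TMM factors there were 1729 and 2261, and 1980 and 2115. Leaving out 1 library gave counts of 3090 (untreated day 0 replicate 1), 2512 (untreated day 0 replicate 2), 3698 (BMP2 day 5 replicate 1) and 3205 (BMP2 day 5 replicate 2). Calls of genes ended without untreated day 0 replicate 1 for MSX2 (3.50), without untreated day 0 replicate 2 for CNN1 (2.31), without BMP2 day 5 replicate 1 for CNN1 (1.95) and NANOG (-4.28) and replicate 2 for NANOG (-4.72), and without any library but those of BMP2 day 10 for POU5F1 (-4.36 to -3.57) or any but those of RA day 5 and BMP2 day 10 and BMP2 day 5 replicate 2 for TNNT2 (1.90 to 4.34).

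BMP2 day 10 against untreated day 0 addresses the middle of muscle induction. Smooth muscle genes stood above the untreated level, and proliferation genes had fallen. The comparison rests on the replicates that lie far apart (r = 0.957). ACTA2 stood at 217 CPM (7.94 ± 0.95, adjusted p = 0.00043), TAGLN, a smooth muscle cytoskeletal gene, rose by 3.56 ± 0.92 and TNNT2 by 4.25 ± 1.15. CDKN1A rose from 8.80 to 238 CPM (4.76 ± 1.24, adjusted p = 0.014) and MKI67 fell from 551 to 131 CPM (-2.07 ± 0.39). COL3A1 rose to 4290 CPM (11.40 ± 2.09). Of 28 cell cycle genes, 26 fell, or 28 adjusted over the list alone (median -1.72, camera adjusted p = 2.2e-13, adjusted p = 0.42 with an estimated correlation). Of 14 smooth muscle and contractile genes, 11 rose, or 13 adjusted over the list alone (median 3.16, camera adjusted p = 2.8e-07, adjusted p = 0.28 with an estimated correlation). Of 13 trophoblast and amnion genes, 7 rose, or 8 adjusted over the list alone (median 4.97, camera adjusted p = 0.0073, adjusted p = 0.44 with an estimated correlation). This call ended without BMP2 day 10 replicate 1 (adjusted p = 0.24). Further lists called by camera were HOX, BMP response and extracellular matrix genes as higher and mismatch repair, base excision repair, homologous recombination, pluripotency, glycolysis and ribosomal protein genes as lower (adjusted p from 2.1e-14 to 0.028, adjusted p from 0.22 to 0.76 with an estimated correlation). Without 1 library, calls ended for glycolysis (0.097) and ribosomal protein (0.59) genes, with the highest adjusted p in brackets. The edgeR test passed 6947 genes, 3799 higher and 3148 lower, of which 5858 were also among the 7856 without BMP2 day 10 replicate 1 and 4873 among the 5812 without BMP2 day 10 replicate 2. With limma on RPKM, 2071 and 2704 were higher and lower (offset 1) and 2368 and 2681 (offset 0.1). These became 2129 and 2740, and 2404 and 2678, with TMM factors. The edgeR count was 4215 without untreated day 0 replicate 1, 3748 without untreated day 0 replicate 2, and 1019 with only the 4 libraries compared. Single genes lost their call without untreated day 0 replicate 1 for CDKN1A (4.56), TAGLN (2.99) and TNNT2 (3.69), without untreated day 0 replicate 2 for CDKN1A (5.00) and TNNT2 (5.20), and without BMP2 day 10 replicate 2 for CDKN1A (0.33) and TNNT2 (2.38). With only the 4 libraries compared, the calls of CDKN1A (4.78), COL3A1 (11.4), MKI67 (-2.04), TAGLN (3.58) and TNNT2 (4.28) ended.

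BMP2 day 21 against untreated day 0 describes the end of muscle induction. Extracellular matrix genes rose far above the untreated level: COL3A1 (ENSG00000168542) rose from 1.63 to 20800 CPM (13.67 ± 2.25, adjusted p = 0.0009), LUM, a small proteoglycan gene, from 0.322 to 4590 CPM (13.81 ± 1.15), and ASPN was at least 2000-fold higher. TNNT2 rose by 4.68 ± 1.17 and ACTA2 by 7.18 ± 0.92, while TAGLN had 2.19 ± 0.87 (adjusted p = 0.062) and DES, muscle desmin, had -1.17 ± 0.52 (adjusted p = 0.089). MYOD1 and MYOG, master factor genes of skeletal muscle, had too few counts to be tested. NES, a progenitor filament gene, fell from 406 to 15.6 CPM (-4.70 ± 0.98) and MKI67 from 551 to 68.6 CPM (-3.01 ± 0.41), while CDKN1A rose to 392 CPM (5.48 ± 1.29). Of 21 extracellular matrix genes, 19 rose and 1 fell, the same numbers adjusted over the list alone (median 4.54, camera adjusted p = 1.4e-11, adjusted p = 0.27 with an estimated correlation). Of 14 smooth muscle and contractile genes, 9 rose, or 10 adjusted over the list alone (median 2.32, camera adjusted p = 0.0012, adjusted p = 0.43 with an estimated correlation). Of 17 cardiac muscle genes, 4 rose and 4 fell, the same numbers adjusted over the list alone (median 0.43, camera adjusted p = 0.84). Of 19 skeletal muscle genes, 2 rose and 4 fell, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.86). All 28 cell cycle genes fell, as they did adjusted over the list alone (median -2.87, camera adjusted p = 4.5e-20, adjusted p = 0.35 with an estimated correlation). Of 22 pluripotency genes, 19 fell, or 21 adjusted over the list alone (median -6.58, camera adjusted p = 2.5e-14, adjusted p = 0.27 with an estimated correlation). Camera also called HOX genes as higher and glycolysis genes as lower (adjusted p from 1.3e-07 to 0.00026, adjusted p from 0.40 to 0.41 with an estimated correlation). With edgeR, 9012 genes passed, 4784 higher and 4228 lower. On RPKM, limma called 2794 and 3539 higher and lower (offset 1) and 2978 and 3565 (offset 0.1). Division by TMM factors gave 3006 and 3429, and 3158 and 3438. Without untreated day 0 replicate 1 the calls of CDKN1A (5.27) and TNNT2 (4.12) ended, and TAGLN passed without RA day 5 replicate 1 or 2 (2.19 and 2.21), with DESeq2 (2.16) and with only the 4 libraries compared (2.15).

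**Figure D2:**
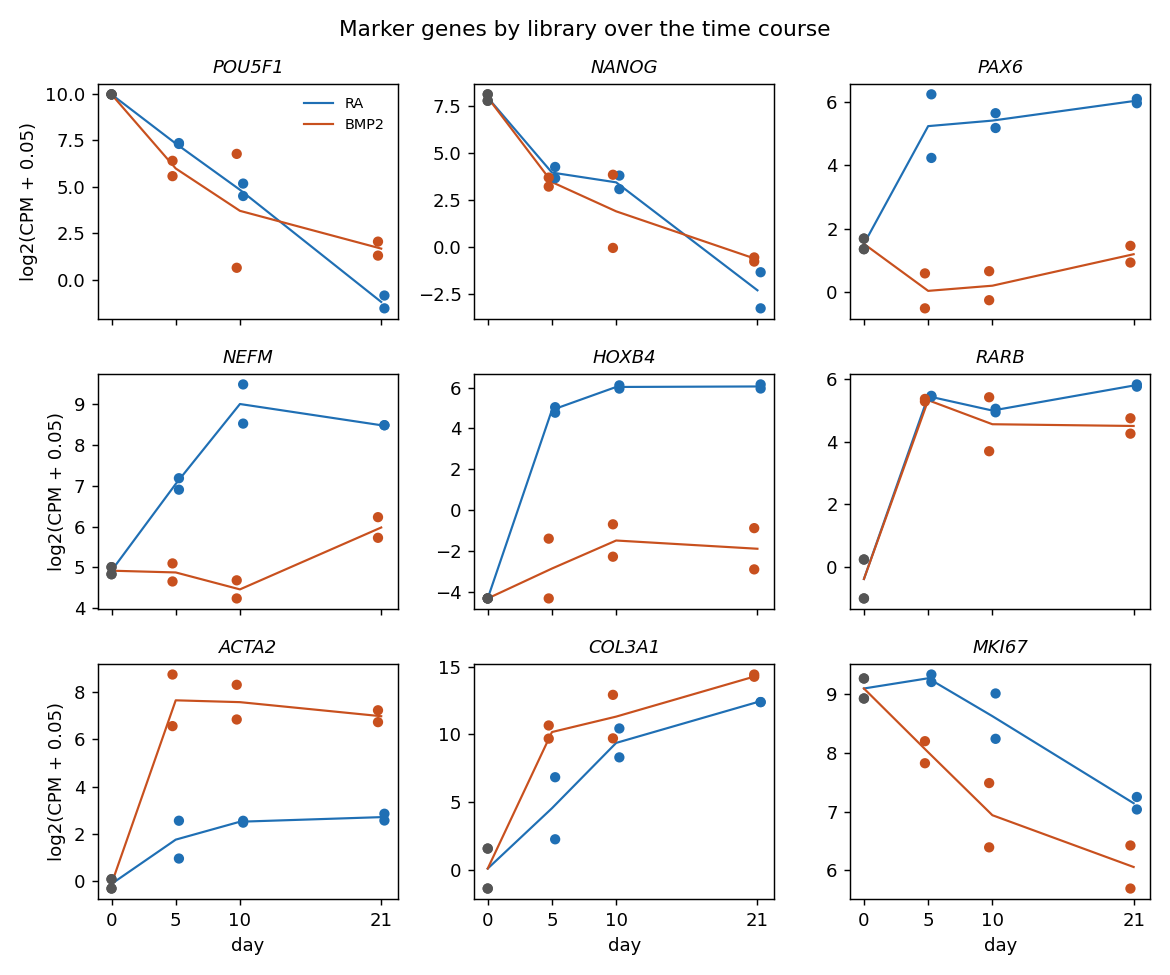
log2(CPM + 0.05) of 9 marker genes against day (0, 5, 10 and 21), each point a library and each line the mean of a group, in RA and BMP2. NANOG fell in both treatments, PAX6 rose under RA, and ACTA2 stood higher under BMP2 than under RA at each day.

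RA against BMP2 at day 5 asks where the treatments differed first. PAX6 (log2 fold change 5.51 ± 0.70, adjusted p = 0.0021) and CYP26A1 (4.81 ± 0.82) were higher under RA. RARB did not pass the test, at 44.0 against 40.4 CPM (0.13 ± 0.48, adjusted p = 0.90). ACTA2 (-6.10 ± 0.86), the fibronectin gene FN1 (-3.67 ± 0.57), HAND1 (-5.78 ± 1.34) and BMP4 (-2.45 ± 0.53) were lower under RA. Of 39 HOX genes, 20 were higher and 7 lower under RA, or 22 and 9 adjusted over the list alone (median 3.34, camera adjusted p = 1.2e-11, adjusted p = 0.28 with an estimated correlation). Extracellular matrix genes were lower under RA in 14 of 21 cases, or 17 adjusted over the list alone (median -2.73, camera adjusted p = 2.1e-14, adjusted p = 0.27 with an estimated correlation). Of 28 cell cycle genes, 5 were higher under RA, or 11 adjusted over the list alone (median 0.92, camera adjusted p = 1.5e-07, adjusted p = 0.52 with an estimated correlation). The edgeR test passed 2338 genes, 1142 higher and 1196 lower under RA, and DESeq2 called 4145. Higher and lower calls of limma on RPKM were 1234 and 696 (offset 1) and 1111 and 790 (offset 0.1). They were 1025 and 757, and 933 and 872, with TMM factors. With 1 library left out, the count was 1351 and 502 (RA day 5 replicates 1 and 2), 888 and 1040 (BMP2 day 5 replicates 1 and 2), 1471 and 1469 (RA day 21 replicates 1 and 2), and 4206 and 4221 (BMP2 day 10 replicates 1 and 2). Gene calls ended without RA day 5 replicate 2 for BMP4 (-1.81) and HAND1 (-4.83), BMP2 day 5 replicate 1 for BMP4 (-2.06) and HAND1 (-5.89), and BMP2 day 5 replicate 2 for HAND1 (-5.67). They also ended for BMP4 (-2.47) and HAND1 (-5.80) with only the 4 libraries compared.

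RA against BMP2 at day 10 involves the BMP2 replicates with r = 0.957. NEFM was higher under RA, at 544 against 22.2 CPM (4.61 ± 0.36, adjusted p = 0.00031), as were MAP2 (1.77 ± 0.36) and DCX (2.68 ± 0.62). ACTA2 (-5.26 ± 0.83), the cardiac factor gene TBX20 (-7.15 ± 0.86) and the keratin gene KRT19 (-3.73 ± 0.41) were lower under RA. Of 25 neuronal genes, 8 were higher and 1 lower under RA, or 11 and 4 adjusted over the list alone (median 1.30, camera adjusted p = 0.0004, adjusted p = 0.27 with an estimated correlation). Of 18 neural progenitor and proneural genes, 7 were higher, or 10 adjusted over the list alone (median 4.19, camera adjusted p = 4.8e-09, adjusted p = 0.27 with an estimated correlation). Of 14 epithelial genes, 3 were lower under RA, or 4 adjusted over the list alone (median -1.71, camera adjusted p = 0.00083, adjusted p = 0.44 with an estimated correlation). Without BMP2 day 10 replicate 1 the epithelial list turned direction (adjusted p = 0.90). With edgeR, 2075 genes passed, 979 higher and 1096 lower under RA, against 3930 in DESeq2 and 9 with only the 4 libraries compared. Tested by limma, RPKM gave 1426 and 441 higher and lower (offset 1) and 1400 and 487 (offset 0.1). After division by TMM factors there were 678 and 659, and 731 and 771. Without 1 library, the edgeR count was 683 and 619 (RA day 10 replicates 1 and 2), 1245 and 1250 (RA day 21 replicates 1 and 2), and 4435 (BMP2 day 10 replicate 1). Calls of genes ended without RA day 10 replicate 1 for DCX (2.33) and MAP2 (1.83), RA day 10 replicate 2 for ACTA2 (-5.23), DCX (2.93) and MAP2 (1.68), and BMP2 day 10 replicate 2 for DCX (2.28) and MAP2 (1.45). With only the 4 libraries compared, the calls of NEFM (4.61), MAP2 (1.76), DCX (2.67), ACTA2 (-5.25), TBX20 (-7.15) and KRT19 (-3.73) ended.

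RA against BMP2 at day 21 compares both end points. CYP26B1 was higher under RA, at 865 against 0.853 CPM (9.98 ± 1.08, adjusted p = 0.0012), as were PAX6 (4.85 ± 0.68), MAP2 (2.16 ± 0.37), and ID3 (2.94 ± 0.41). DCX was lower under RA (-2.58 ± 0.62, adjusted p = 0.027), as were LUM (-7.61 ± 0.90), COL6A3 (-8.39 ± 0.84) and ACTA2 (-4.30 ± 0.79). Of 21 extracellular matrix genes, 14 were lower under RA, or 14 with 1 higher adjusted over the list alone (median -2.33, camera adjusted p = 4.4e-13, adjusted p = 0.27 with an estimated correlation). Of 14 smooth muscle and contractile genes, 4 were lower and 1 higher, or 5 and 1 adjusted over the list alone (median -1.23, camera adjusted p = 0.0031, adjusted p = 0.44 with an estimated correlation). Of 25 neuronal genes, 2 were higher and 3 lower, or 3 and 4 adjusted over the list alone (median 0.05, with a test pointing down, camera adjusted p = 0.96). The edgeR test passed 2308 genes, 1146 higher and 1162 lower under RA, against 4176 in DESeq2 and 5326 with only the 4 libraries compared. With limma on RPKM, 1886 and 658 were higher and lower (offset 1) and 1864 and 685 (offset 0.1). These became 1069 and 894, and 1003 and 916, with TMM factors. With 1 library left out, the edgeR count was 289 and 344 (RA day 21 replicates 1 and 2), 1081 and 626 (BMP2 day 21 replicates 1 and 2), and 4229 and 4212 (BMP2 day 10 replicates 1 and 2). Single genes lost their call without RA day 21 replicate 1 for ACTA2 (-4.18) and DCX (-2.87), RA day 21 replicate 2 for ACTA2 (-4.47), DCX (-2.37) and MAP2 (1.95), and BMP2 day 21 replicate 2 for DCX (-2.16).

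Within the RA series, day 21 against day 5 shows what changed late. CYP26A1 fell from 485 to 92.6 CPM (-2.39 ± 0.73, adjusted p = 0.035), while ID3 rose by 2.19 ± 0.40. MKI67 fell, at -2.13 ± 0.39. Of 51 NER genes, 4 rose and 19 fell, the same numbers adjusted over the list alone. In edgeR 5503 genes passed, 2664 higher and 2839 lower, and 8884 with only the 4 libraries compared. On RPKM, limma called 2389 and 2038 higher and lower (offset 1) and 2372 and 2071 (offset 0.1). Division by TMM factors gave 1979 and 2327, and 2000 and 2415. Leaving out 1 library gave 3085 and 2417 (RA day 5 replicates 1 and 2) and 2145 and 1913 (RA day 21 replicates 1 and 2). The call of CYP26A1 ended without RA day 5 replicates 1 and 2 (-1.96 and -2.74) and RA day 21 replicates 1 and 2 (-2.37 and -2.48).

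Within the BMP2 series, day 21 against day 5 gave fewer calls. NES fell from 764 to 15.6 CPM (-5.61 ± 1.02, adjusted p = 0.014) and ID1 from 97.9 to 26.5 CPM (-1.89 ± 0.36), and CDKN1A rose from 13.8 to 392 CPM (4.83 ± 1.25). DDB2, a lesion recognition gene, rose by 1.86 ± 0.55 (adjusted p = 0.047). Of 51 NER genes, 3 rose and 13 fell, or 4 and 16 adjusted over the list alone. In edgeR 2972 genes passed, 1488 higher and 1484 lower, against 5165 in DESeq2. Higher and lower calls of limma on RPKM were 1017 and 1292 (offset 1) and 1037 and 1498 (offset 0.1). They were 1169 and 1192, and 1126 and 1315, with TMM factors. Without 1 library, the number was 1 and 992 (BMP2 day 5 replicates 1 and 2), 878 and 91 (BMP2 day 21 replicates 1 and 2), 1957 and 1954 (untreated day 0 replicates 1 and 2), 1475 and 1476 (RA day 21 replicates 1 and 2), and 5288 and 5306 (BMP2 day 10 replicates 1 and 2). Gene calls ended without BMP2 day 5 replicate 1 for NES (-5.87) and ID1 (-2.17), BMP2 day 5 replicate 2 for ID1 (-1.56), BMP2 day 21 replicates 1 and 2 for NES (-5.30 and -6.02) and ID1 (-2.07 and -1.73), any library of untreated day 0, RA day 21, BMP2 day 5 or BMP2 day 21 for CDKN1A (4.38 to 5.21), and any library but those of BMP2 day 10 for DDB2 (1.5 to 2.30).

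The changes of RA and of BMP2 against the shared day 0 libraries overlapped at each day. At day 21, 6243 genes changed the same way in both treatments, 3243 higher and 3000 lower, and 74 in opposite directions. Independent lists of these sizes would share 2014 genes in the same and 2001 in opposite directions, a figure that leaves out the effect of the shared day 0 libraries. At day 10 the numbers were 3302 the same way and 37 opposite, against 839 and 827, and at day 5 they were 1157 and 23, against 240 and 226. Log2 fold changes of 14525 genes correlated across genes with r = 0.64, 0.71 and 0.79 at days 5, 10 and 21. In 20 simulations of unchanged groups against shared day 0 libraries, r was 0.50. The edgeR overlaps there were 0 in the same and 0 in opposite directions. Since no gene changed in them, they cannot show how many shared calls the common day 0 libraries add among changed genes. The covariance was 1.40, 2.02 and 3.52, against 0.11 simulated. Without 1 library, the day 5 overlap was 404 and 243 (untreated day 0 replicates 1 and 2), 332 and 745 (RA day 5 replicates 1 and 2), 701 and 704 (RA day 21 replicates 1 and 2), and 2008 and 2006 (BMP2 day 10 replicates 1 and 2). The day 10 overlap was 1741 and 1073 without untreated day 0 replicates 1 and 2 and 1467 without RA day 10 replicate 1, the day 21 overlap 3879 without untreated day 0 replicate 2, and DESeq2 gave 2248 genes at day 5.

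The study's question makes the NER genes the central group. Late in both treatments most genes of repair synthesis fell, while single genes of the other steps rose and as many or more of each of those steps fell. The steps were not tested against each other. At RA day 21, of 51 NER genes tested, 7 rose and 25 fell, or 10 and 26 adjusted over the list alone. At BMP2 day 21, 9 rose and 25 fell, or 12 and 26 adjusted over the list alone. ERCC1 (ENSG00000012061) and ERCC4, which together form the nuclease that cuts on the 5' side of a lesion, rose under RA by 0.99 ± 0.18 (adjusted p = 0.0017) and 0.98 ± 0.23 on the log2 scale, and under BMP2 by 1.00 ± 0.18 and 1.06 ± 0.23. ERCC1 was the NER gene that had also risen by RA day 5 (0.91 ± 0.18, adjusted p = 0.015). XPC, the lesion sensor of global repair, rose by 0.56 ± 0.15 under RA and 0.71 ± 0.15 under BMP2. ERCC6 (ENSG00000225830), which couples repair to stalled transcription, rose by 0.65 ± 0.23 under RA and 1.56 ± 0.23 under BMP2, from 13 to 38.3 CPM. UVSSA, which acts with it, rose by 0.65 ± 0.19 and 0.82 ± 0.19. The elongation factor gene TCEA1 fell, at -1.88 ± 0.21 and -1.45 ± 0.20, as did the deubiquitinase gene USP7, at -1.25 ± 0.16 and -1.14 ± 0.16. The sliding clamp gene PCNA (ENSG00000132646) fell from 304 to 122 CPM under RA (-1.32 ± 0.16, adjusted p = 0.00025) and to 110 CPM under BMP2 (-1.47 ± 0.16). RFC3 of the clamp loader fell, at -2.32 ± 0.32 and -2.41 ± 0.32, and the ligase gene LIG1 at -1.37 ± 0.24 and -1.73 ± 0.25. Calls of genes ended at RA day 5 without untreated day 0 replicates 1 and 2 (1.00 and 0.82) and RA day 5 replicate 1 (0.75) for ERCC1. They ended at RA day 21 without untreated day 0 replicate 1 (0.51) and RA day 21 replicate 2 (0.50) for XPC, without untreated day 0 replicates 1 and 2 (0.65 and 0.66) and RA day 21 replicates 1 and 2 (0.61 and 0.67) for UVSSA, and without any library but those of BMP2 days 10 and 21 for ERCC6 (0.50 to 0.81).

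By step of the pathway, gap filling and ligation was the NER list that camera called. At RA day 21, 12 of its 18 genes fell and 1 rose, or 13 and 2 adjusted over the list alone (median -1.29, camera adjusted p = 0.0005, adjusted p = 0.42 with an estimated correlation). At BMP2 day 21, 13 fell and 2 rose, the same numbers adjusted over the list alone (median -1.67, camera adjusted p = 3.4e-05, adjusted p = 0.39 with an estimated correlation). At BMP2 day 10, 12 fell and 1 rose, or 13 and 1 adjusted over the list alone (median -1.06, camera adjusted p = 0.0004, adjusted p = 0.42 with an estimated correlation). At BMP2 day 5, 5 fell and 1 rose, or 6 and 1 adjusted over the list alone (median -0.64, camera adjusted p = 0.017, adjusted p = 0.52 with an estimated correlation), and the call ended without BMP2 day 5 replicate 2 (adjusted p = 0.12). At RA day 5, 0 of the 18 passed either way (median -0.12, camera adjusted p = 0.74). At RA day 10, 1 fell and 0 passed adjusted over the list alone (median -0.51, camera adjusted p = 0.051). At RA day 10 the list passed without RA day 5 replicate 1 (adjusted p = 0.048), RA day 10 replicate 2 (0.040), RA day 21 replicates 1 and 2 (0.048 each), BMP2 day 5 replicate 1 (0.044), BMP2 day 10 replicates 1 and 2 (0.025 and 0.024) and BMP2 day 21 replicates 1 and 2 (0.040 and 0.045). With all libraries and an estimated correlation it had adjusted p = 0.58, and those fits were not run with one. POLD4, a small polymerase delta subunit, was the gene of this list that rose under RA (1.62 ± 0.46) and, with the translesion polymerase gene POLK (0.99 ± 0.37), under BMP2 (2.18 ± 0.47). The RA call of POLD4 ended without untreated day 0 replicate 2 (1.17) and RA day 21 replicate 2 (1.44), and that of POLK without any library but those of BMP2 day 10 and BMP2 day 21 replicate 1 (0.67 to 1.06).

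Camera called the other NER lists in no comparison with day 0. With no low-count filter it called the transcription-coupled factors at RA day 10 (adjusted p = 0.046). The fry calls of these factors in each comparison (adjusted p from 0.0011 to 0.012) do not set them apart. Of 9 lesion recognition genes at RA day 21, 1 rose and 2 fell, the same numbers adjusted over the list alone, with a median of 0.18 and a test pointing down (camera adjusted p = 0.79). At BMP2 day 21, 1 rose (XPC) and 1 fell (RAD23B, at -0.75 ± 0.17) either way (camera adjusted p = 0.91). Of 16 unwinding, verification and incision genes at RA day 21, 3 rose and 7 fell, or 5 and 7 adjusted over the list alone (median -0.19, camera adjusted p = 0.45). The 7 included the RPA subunit genes RPA1, RPA2 and RPA3, at -0.99 ± 0.24, -0.97 ± 0.18 and -1.19 ± 0.30. At BMP2 day 21, 4 rose and 5 fell, or 5 and 6 adjusted over the list alone (median -0.30, camera adjusted p = 0.53), GTF2H1 of the helicase complex TFIIH and the nuclease gene ERCC5 among those risen (0.89 ± 0.24 and 0.73 ± 0.22). Of 8 transcription-coupled factors, 2 rose and 4 fell at RA day 21 either way (median -0.50, camera adjusted p = 0.11). At BMP2 day 21, 2 rose and 6 fell either way (median -0.66, camera adjusted p = 0.22). GTF2H4 had too few counts to be tested. Single genes lost their call without untreated day 0 replicate 1 for RPA3 (-1.09), GTF2H1 (0.74) and ERCC5 (0.67), untreated day 0 replicate 2 for ERCC5 (0.78), RA day 21 replicates 1 and 2 for RPA1 (-1.01 and -1.0), RA day 21 replicate 2 for RPA3 (-1.14), and BMP2 day 21 replicate 2 for GTF2H1 (0.84) and ERCC5 (0.60).

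**Figure D3:**
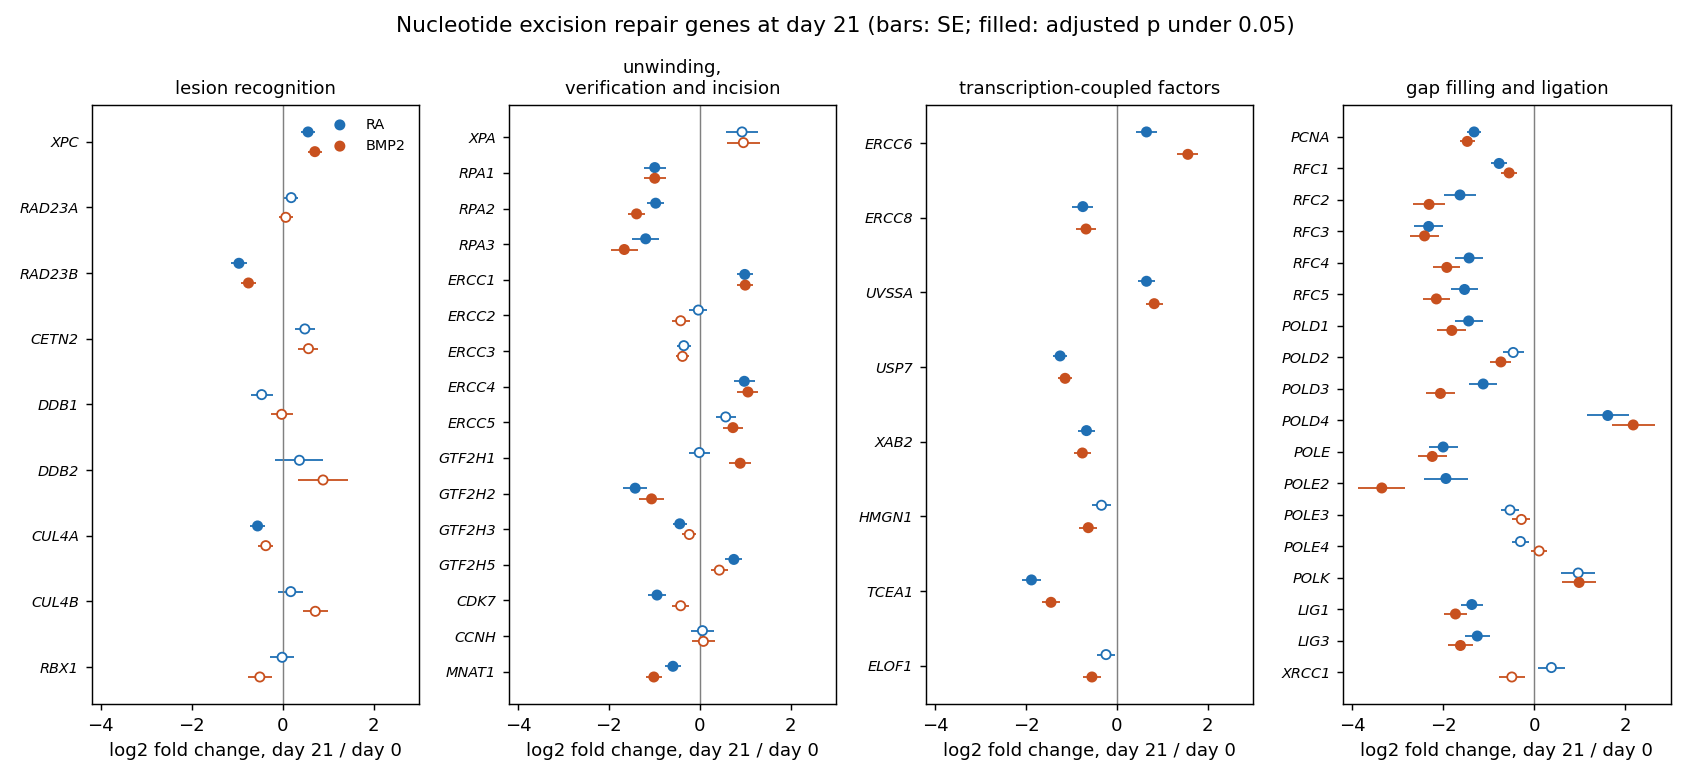
Log2 fold change from day 0 to day 21 of the 51 NER genes tested, in RA and BMP2, by step of the pathway; bars are SE and filled points have adjusted p under 0.05. ERCC1, ERCC4, ERCC6 and UVSSA lie above 0 in both treatments, and PCNA, the RFC genes and LIG1 below it.

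Between the treatments, few NER genes passed the test. At day 5 PCNA (1.03 ± 0.16, adjusted p = 0.0045), RPA2 (0.79 ± 0.18) and RFC5 (1.09 ± 0.29) were higher under RA. At day 10 PCNA (0.82 ± 0.16) and LIG1 (0.98 ± 0.24) were higher under RA. At day 21 GTF2H1 (-0.90 ± 0.24, adjusted p = 0.035) and ERCC6 (-0.91 ± 0.23, adjusted p = 0.03) were lower under RA. Of the 18 gap filling and ligation genes, 2 were higher under RA at day 5, or 4 adjusted over the list alone (median 0.59, camera adjusted p = 0.0074, adjusted p = 0.50 with an estimated correlation). The day 5 call ended without BMP2 day 5 replicate 2 (adjusted p = 0.11). At day 10, 2 were higher either way (median 0.49, camera adjusted p = 0.013, adjusted p = 0.52 with an estimated correlation). The call ended without RA day 10 replicate 2 (adjusted p = 0.073) and without BMP2 day 10 replicate 2 (adjusted p = 0.17). At day 21, 0 passed either way (median 0.32, camera adjusted p = 0.21). Camera called the other 3 NER lists at no day (adjusted p from 0.22 to 0.92). At day 10 fry called lesion recognition as lower under RA (adjusted p = 0.019), where 0 of 9 genes passed either way. Gene calls ended without RA day 5 replicates 1 and 2 (0.83 and 0.75) and BMP2 day 5 replicates 1 and 2 (0.89 and 0.70) for RPA2, without RA day 10 replicates 1 and 2 (0.84 and 0.78) for PCNA at day 10, and without RA day 21 replicates 1 and 2 (-0.84 and -1.02) and BMP2 day 21 replicate 2 (-0.66) for ERCC6. The RFC5 call ended without any library but those of BMP2 days 10 and 21 (0.92 to 1.27), that of GTF2H1 without any library of untreated day 0, RA day 21 or BMP2 day 21 or RA day 5 replicate 1 (-0.97 to -0.86), and that of LIG1 without any library of untreated day 0, RA day 10 or RA day 21, RA day 5 replicate 2 or BMP2 day 10 replicate 2 (0.68 to 1.05). At day 10 the calls of PCNA (0.82) and LIG1 (0.97) ended with only the 4 libraries compared.

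Genes of the other repair pathways mostly fell by day 21. Of 18 homologous recombination genes, 12 fell under RA, as many as adjusted over the list alone (median -1.17, camera adjusted p = 8e-05, adjusted p = 0.38 with an estimated correlation). Under BMP2, 13 fell, as many as adjusted over the list alone (median -1.58, camera adjusted p = 5.5e-06, adjusted p = 0.32 with an estimated correlation), with the helicase gene BLM at -2.85 ± 0.31 under RA and -3.63 ± 0.32 under BMP2. Of 8 mismatch repair genes, 6 fell in each treatment, as many as adjusted over the list alone, with camera adjusted p = 0.0023 under RA and 0.0019 under BMP2 (adjusted p = 0.41 with an estimated correlation in both). Of 17 base excision repair genes, 10 fell and 2 rose under RA, or 10 and 3 adjusted over the list alone (median -0.87, camera adjusted p = 0.015, adjusted p = 0.43 with an estimated correlation). Under BMP2, 10 fell and 1 rose, the same numbers adjusted over the list alone (median -0.75, camera adjusted p = 0.0009, adjusted p = 0.35 with an estimated correlation), and PARP1 fell, at -2.14 ± 0.24 and -2.34 ± 0.24. Of 8 non-homologous end joining genes, 3 fell and 1 rose under RA, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.071), and 4 fell under BMP2, or 4 with 2 risen adjusted over the list alone (camera adjusted p = 0.19). Cell cycle genes fell over the same days, as given above with their values.

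HOX genes moved in an order along their clusters under RA, and hardly so under BMP2. Across the 39 genes, Spearman's rho of the log2 fold change against day 0 with paralog number was -0.64, -0.65 and -0.54 under RA at days 5, 10 and 21, and 0.15, 0.20 and 0.19 under BMP2. Of 12 HOX genes of paralog groups 1 to 4, 12 rose by RA day 5, against 9 of 11 in groups 5 to 8 and 4 of 16 in groups 9 to 13. By RA day 21 the numbers were 11, 11 and 9. Under BMP2 at day 5 they were 7, 8 and 12, and at day 21 they were 7, 8 and 13, with 1 of groups 1 to 4 fallen at each. The median level at day 5 in groups 1 to 4 was 49.2 CPM under RA and 0.265 CPM under BMP2, and in groups 9 to 13 it was 0.947 and 3.52 CPM. Against BMP2, RA was higher in all 12 genes of groups 1 to 4 at day 5, and lower in 7 of 16 and higher in 1 of groups 9 to 13. The log2 ratio of RA to BMP2 fell with paralog number, with a rho of -0.86, -0.85 and -0.78 at days 5, 10 and 21, where genes of a cluster are not independent. HOXB4 was at 66.5 CPM under RA and 0.288 CPM under BMP2 at day 21 (7.83 ± 1.07, adjusted p = 0.0039), while HOXA11, with no count at day 0, was at least 300-fold higher under BMP2.

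**Figure D4:**
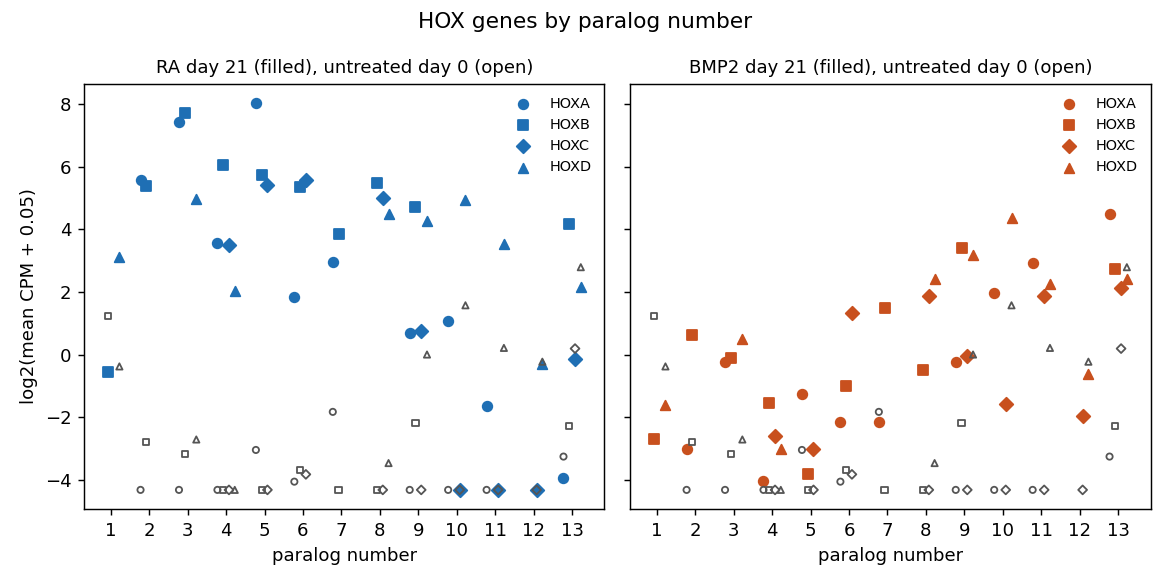
log2(mean CPM + 0.05) of 38 HOX genes at day 21 (filled) and untreated day 0 (open) against paralog number, under RA and under BMP2, with a marker for each cluster. Under RA HOXB4 reaches 66.5 CPM, and under BMP2 the genes of groups 9 to 13 a median of 4.51 CPM.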

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

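The results below differed between RA and BMP2 at the same day by a direct test, and all tests of explanations here were chosen after the results were seen, except the test of different distances along a course and the test of overlapping genes.

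Among NER genes, RPA2, PCNA and RFC5 were higher under RA at day 5 (log2 fold changes 0.79, 1.03 and 1.09) and PCNA and LIG1 at day 10 (0.82 and 0.98). GTF2H1 and ERCC6 were lower under RA at day 21 (-0.90 and -0.91). Among the fixed markers at day 21, SOX2 (2.29), MAP2 (2.16), PAX6 (4.85), HOXB4 (7.83), CYP26A1 (3.13), ID1 (1.98) and ID3 (2.94) were higher under RA. DCX (-2.58), ACTA2 (-4.30), CNN1 (-3.30), DES (-3.44) and TNNT2 (-4.24) were lower. With RA day 21 replicates 1 and 2 left out in turn, the calls of CYP26A1 (3.17 and 3.06), ID1 (1.91 and 2.01), CNN1 (-3.15 and -3.50) and DES (-3.53 and -3.38) ended. They also ended without BMP2 day 21 replicate 1 for CYP26A1 (2.98), without BMP2 day 21 replicate 2 for CYP26A1 (3.29), ID1 (1.80) and CNN1 (-3.14), without any library but those of BMP2 day 10 for SOX2 (2.14 to 2.43), and without any library of untreated day 0, RA days 10 and 21 or BMP2 day 21 for TNNT2 (-4.38 to -4.11). The report gives these values for the NER genes, MAP2, DCX and ACTA2.

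At day 5, camera called 13 lists between the treatments, with adjusted p from 0.17 to 0.56 with an estimated correlation. Lists higher under RA, with their median log2 fold changes, were HOX (3.34), RA response (2.93), neural progenitor (2.34), pluripotency (1.55), cell cycle (0.92), gap filling (0.59), glycolysis (0.41) and homologous recombination (0.38). Lists lower under RA were extracellular matrix (-2.73), smooth muscle (-1.93), BMP response (-1.37), epithelial (-1.0) and cardiac muscle (-0.76). Without BMP2 day 5 replicate 2, the calls of gap filling (adjusted p = 0.11), glycolysis (0.47), homologous recombination (0.075) and epithelial genes (0.17) ended. Without RA day 5 replicate 2, those of epithelial (0.057) and cardiac genes (0.30) ended. The glycolysis call also ended without RA day 5 replicate 1 (0.066) and BMP2 day 10 replicates 1 and 2 (0.057 and 0.054).

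At day 10, camera called 14 lists, with adjusted p from 0.19 to 0.53 with an estimated correlation. Higher under RA were neural progenitor (4.19), HOX (3.41), RA response (1.81), neuronal (1.30), cell cycle (1.14), pluripotency (0.82), homologous recombination (0.51) and gap filling genes (0.49). Lower were extracellular matrix (-2.52), trophoblast and amnion (-2.37), cardiac muscle (-1.86), epithelial (-1.71), smooth muscle (-1.70) and BMP response genes (-1.21). Without RA day 10 replicate 2, the calls of gap filling (0.073) and homologous recombination (0.066) ended, and without RA day 10 replicate 1 that of trophoblast genes (0.087). Without BMP2 day 10 replicate 2, those of gap filling (0.17) and pluripotency (0.25) ended. Without BMP2 day 10 replicate 1, the trophoblast (0.93) and epithelial lists (0.90) turned direction.

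At day 21, camera called 10 lists, with adjusted p from 0.27 to 0.72 with an estimated correlation. Higher under RA were neural progenitor (2.94), HOX (2.78), RA response (1.92), cell cycle (0.76) and ribosomal protein genes (0.42). Lower were extracellular matrix (-2.33), trophoblast and amnion (-1.34), smooth muscle (-1.23), cardiac muscle (-0.83) and glycolysis genes (-0.42). The ribosomal call ended without BMP2 day 21 replicate 2 (0.74) and the cardiac call without BMP2 day 10 replicates 1 and 2 (0.060 and 0.059). The trophoblast call ended without RA day 21 replicates 1 and 2 (0.054 each) and BMP2 day 5 replicate 2 (0.055).

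The BMP2 day 10 replicates lie far apart, with a chi-square per degree of freedom of 551.8 between them, against 22.6 to 140.4 in the other groups. Deposition of the same library as BMP2 day 5 replicate 2 and BMP2 day 10 replicate 1 would leave a chi-square per degree of freedom near 2, and it was 42.2. That the cultures had gone different distances along a shared course stays open as a hypothesis: the difference between the replicates correlated across genes with the change from day 5 to day 21 at r = 0.64. Whether labels were exchanged with a BMP2 day 5 or day 21 library also stays open. Their order on the day 5 to day 21 axis cannot decide it. Both day 5 libraries had higher positions (0.24 and 0.16) than BMP2 day 10 replicate 1 (0.03). Each day 5 library was placed against the other day 5 library alone, and the day 10 library against the mean of both. After any exchange, BMP2 day 10 replicate 2 would share a group with a day 5 library, or replicate 1 with a day 21 library. These correlated at r = 0.971 and 0.958, and at r = 0.955 and 0.948, so a pair would still lie apart. A wrong label without a partner, and the BMP2 dose, which the labels do not give per library, were not tested.

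HOX genes and RARB rose under BMP2 as well as under RA. RNA or reads carried over from RA libraries would leave the same small share of each RA-induced gene. HOX paralogs 5 to 13 and RARB stood at a median of 46.6% of their RA day 5 level at BMP2 day 5 (0.209% to 6920% over 18 genes), RARB at 91.5%. CYP26A1 stood at 0.7%, and 81 other RA-induced genes at a median of 27.2%. These values argue against carry-over for HOX paralogs 5 to 13 and RARB as a set, but not for each of these genes. For HOX paralogs 1 to 4, at a median of 2.52%, carry-over stays open, where the 10th percentile of 81 other RA-induced genes was 0.319% (the division was made after the undivided median of 23.2% over 25 genes was seen). Whether reads shared with overlapping genes add to the rise stays open: of the 7 HOX genes with under 0.1 of their span in other genes, 4 rose at BMP2 day 5 and 3 at day 21, against 27 and 28 of all 39, too few to decide. The time in culture cannot be told apart from the factor, with 0 untreated libraries after day 0.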

How the results depend on the processing

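Fits without both BMP2 day 10 libraries and without both RA day 21 libraries, alone and with an estimated correlation, and limma on RPKM with TMM factors were chosen after the data were seen. A library left alone in its group is assumed to vary like the other groups. Except where stated, the cause was not tested.

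RLE factors, no low-count filter, the CPM filter, robust dispersions, the replicate block and limma on RPKM with either offset kept each of the 11 counts of genes within 1.5 times. The share of higher against lower calls did move with limma on RPKM, which tests 11641 genes and, as deposited, holds no TMM factors. For RA against BMP2 it was 1426 and 441 at day 10 and 1886 and 658 at day 21 with an offset of 1, against 979 and 1096, and 1146 and 1162, in edgeR, and 961 of 2075 and 1280 of 2308 calls were shared. With TMM factors it came back to 678 and 659 (1337 in all, against 2075) and 1069 and 894, so those splits depend on the scaling. For BMP2 against day 0, limma on RPKM gave more lower than higher calls at each day with or without TMM factors, and edgeR more higher than lower. For RA against day 0 the majority at day 10 was higher without TMM factors (1987 and 1275) and lower with them (1279 and 2132). The direction in which most genes moved is therefore not settled for these comparisons. A 2-fold minimum moved the count at RA day 10 from 4593 to 2959, since fewer genes can pass it. DESeq2 moved 5 counts, to 3236 at RA day 5, 4145, 3930 and 4176 for RA against BMP2 at days 5, 10 and 21, and 5165 for BMP2 day 21 against day 5. With only the 4 libraries compared, 5 counts moved, to 2839 at RA day 5, 1019 at BMP2 day 10, 9 and 5326 for RA against BMP2 at days 10 and 21, and 8884 for RA day 21 against day 5. Without both BMP2 day 10 libraries, 4 counts moved, to 2879 at RA day 5, 4288 and 4385 for RA against BMP2 at days 5 and 21, and 5412 for BMP2 day 21 against day 5. Without both RA day 21 libraries they were 1015 at RA day 5, 1518 and 1276 for RA against BMP2 at days 5 and 10, and 1526 for BMP2 day 21 against day 5.

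Leaving out 1 library at a time moved 54 of 154 counts. The counts ran from 345 to 2810 at RA day 5, 1500 to 6368 at RA day 10, 5271 to 9850 at RA day 21, 2512 to 7222 at BMP2 day 5, 3748 to 7856 at BMP2 day 10 and 6159 to 10121 at BMP2 day 21. They ran from 502 to 4221, 619 to 4435 and 289 to 4229 for RA against BMP2 at days 5, 10 and 21, from 1913 to 7209 for RA day 21 against day 5, and from 1 to 5306 for BMP2 day 21 against day 5. The lowest came without a library of a compared group, and the highest without a BMP2 day 10 library, whose replicates differ most. The overlap of RA and BMP2 ran from 243 to 2008 at day 5, 1073 to 4043 at day 10 and 3879 to 7282 at day 21. At day 5 it was 2248 with DESeq2, 2048 without both BMP2 day 10 libraries and 738 without both RA day 21 libraries. Replicate numbers did not pair libraries: over 21 pairs of groups, replicate differences correlated at a median r of 0, from -0.34 to 0.15, with 3 above 0.1 and 2 below -0.1.

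For 154 values of named genes, 0 turned direction with DESeq2, RLE factors, the block, only the 4 libraries compared or 1 library left out. DESeq2 kept each call and added 1, RLE factors ended 2 (ERCC6 at RA day 21, 0.59, and POLK at BMP2 day 21, 0.96), the replicate block ended 8 and the fit with only the 4 libraries compared ended 15. Those under the block were NODAL and LEFTY1 at RA day 5 (3.86 and 3.27), ERCC6 at RA day 21 (0.64), POU5F1 and TNNT2 at BMP2 day 5 (-3.87 and 3.38), SOX2 and TNNT2 for RA against BMP2 at day 21 (2.30 and -4.24) and DDB2 for BMP2 day 21 against day 5 (1.80). Those with only the 4 libraries compared were 2 for RA against BMP2 at day 5, 8 at day 10, and 5 at BMP2 day 10 against day 0. Leaving out 1 library kept 1904 of 2156 results, ended 247 calls and added 5.

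Of 113 calls of lists, 0 stayed with an estimated correlation, 90 with fry, 111 with RLE factors, 112 with no filter and 112 with the block. Leaving out 1 library kept 1524 of 1582 calls, ended 55 and turned 3. Those turned were a list at BMP2 day 10 without BMP2 day 10 replicate 2 (adjusted p = 0.99, range 1.2e-06 to 0.99), and, for RA against BMP2 at day 10 without BMP2 day 10 replicate 1, the trophoblast (0.93, range 7.6e-06 to 0.93) and epithelial genes (0.90, range 8.8e-11 to 0.90). A list without a call also turned: at day 10 it pointed lower under RA than under BMP2 (0.42) and passed as higher without BMP2 day 10 replicate 2 (0.0015, range 9.1e-05 to 0.49). Without both BMP2 day 10 libraries 80 of 85 calls stayed, and 7 of 85 with an estimated correlation, among them pluripotency in each of 5 comparisons with day 0 (adjusted p = 0.027). Without both RA day 21 libraries 92 of 92 stayed, and 0 with an estimated correlation.

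For NER gap filling and ligation, an estimated correlation gave adjusted p = 0.42 at RA day 21 and 0.52, 0.42 and 0.39 at BMP2 days 5, 10 and 21. Without both BMP2 day 10 libraries these were 0.45 at RA day 21, 0.54 at BMP2 day 5 and 0.40 at BMP2 day 21, and without both RA day 21 libraries 0.55, 0.46 and 0.45 at BMP2 days 5, 10 and 21. At RA day 10, where the list had adjusted p = 0.051 (0.58 with an estimated correlation), it passed with RLE factors (0.049), no filter (0.012), the block (0.043) and without both BMP2 day 10 libraries (0.036), and ran from 0.024 to 0.12 with 1 library left out. At BMP2 day 5 it ended without BMP2 day 5 replicate 2, with a range from 0.0023 to 0.12. The transcription-coupled factors passed with fry, at 0.012, 0.0024 and 0.0011 at RA days 5, 10 and 21 and 0.0033, 0.0029 and 0.0018 at BMP2 days 5, 10 and 21, and with no filter at RA day 10 (0.046). Lesion recognition passed with fry for RA against BMP2 at day 10 (0.019, against 0.22 with camera).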

Other observations

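The tests of the hypothesis on gap filling below were all chosen after the results were seen.

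Camera called more lists, but none held throughout. At BMP2 day 21, 6 of 12 endoderm and liver genes rose, or 7 adjusted over the list alone (median 3.09, camera adjusted p = 0.032, adjusted p = 0.35 with an estimated correlation), among them GATA4 (6.88 ± 1.22) and GATA6 (5.70 ± 0.65), factor genes of endoderm and heart. The call ended without untreated day 0 replicate 1 (0.050) and without BMP2 day 10 replicates 1 and 2 (0.056 and 0.054). Of 12 immediate early and stress genes, 6 rose, as many as adjusted over the list alone (median 1.47, camera adjusted p = 0.034, adjusted p = 0.44 with an estimated correlation), including FOSB (6.15 ± 1.24) and ATF3 (2.27 ± 0.71), and the call ended without BMP2 day 21 replicate 1 (0.054). Of 24 ribosomal protein genes, 2 fell, as many as adjusted over the list alone (median -0.49, camera adjusted p = 0.027, adjusted p = 0.76 with an estimated correlation), RPL8 (-1.10 ± 0.27) and RPS2 (-1.01 ± 0.24), and the call ended without BMP2 day 21 replicate 2 (0.34). Of 15 mesoderm genes, 6 rose either way (camera adjusted p = 0.22), with FOXF1 at 6.16 ± 1.12. The calls of RPL8 (-0.82) and RPS2 (-0.77) ended without BMP2 day 21 replicate 2, and that of ATF3 without untreated day 0 replicates 1 and 2 (2.58 and 2.02) and BMP2 day 21 replicate 1 (1.32).

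At RA day 21, camera called none of these lists: 5 of 15 mesoderm genes rose and 1 fell, the same numbers adjusted over the list alone (adjusted p = 0.11), led by OSR1, a factor gene of intermediate mesoderm (8.01 ± 1.44). Of 15 glia and neural crest genes, 5 rose and 5 fell either way (adjusted p = 0.60), with ERBB3 at -5.31 ± 1.01. Of 9 endothelial and blood genes, 2 fell either way (adjusted p = 0.24), TIE1 (-4.55 ± 1.30) and TEK (-1.74 ± 0.46). Of 14 epithelial genes, 7 fell and 1 rose either way (adjusted p = 0.20). EPCAM, an adhesion gene of epithelia and stem cells, was at -3.07 ± 0.77. The calls of TEK and TIE1 ended without untreated day 0 replicate 1 (-1.51 and -3.85) and RA day 21 replicate 2 (-1.65 and -3.77), and without RA day 21 replicate 1 that of TEK (-1.86) ended, as did that of EPCAM without either RA day 21 library (-3.00 and -3.18). The most abundant gene was EEF1A1 in 10 libraries, H19, an imprinted growth transcript, in the RA day 21 libraries (1.70% and 1.55% of counts) and COL3A1 in the BMP2 day 21 libraries (2.05% and 1.80%).

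The fall of NER gap filling genes may follow the fall of cell cycle genes, since clamp, clamp loader and replicative polymerase genes also serve DNA replication. An earlier form over the libraries of each treatment, with 8 relations, was set aside because libraries cluster by day. Over the replicate differences of the 7 groups, gap filling followed cell cycle genes with Pearson's r = 0.99 (adjusted p = 0.0024) and Spearman's rho of 0.96 (adjusted p = 0.011), forms that depend on arbitrary replicate numbers. The transcription-coupled factors passed with rho of 0.86 (adjusted p = 0.048) but not with r = 0.80 (adjusted p = 0.06). For gap filling, the form that does not depend on them, an exact sign-flip test with 128 orders, gave adjusted p = 0.12 (raw 0.031, smallest possible 0.016, same sign in 6 of 7 groups). A list alone could not pass this test, since its smallest possible p adjusted over the 4 lists is 0.062, and the hypothesis stays open. None of 10000 random lists of the same size and expression followed as closely (cosine 0.99 for gap filling), out of 16 relations tried in all. Their genes need not move together, so this cannot set gap filling apart from lists whose genes do. BMP2 day 10 replicates differed most, but r stayed 0.99 without BMP2 days 10 and 21. The sign-flip adjusted p was 0.55 for lesion recognition, 0.55 for unwinding and incision, and 0.16 for the transcription-coupled factors.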
